A study of Canis lupus familiaris with 2 samples.

How the data were processed

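Total RNA from 1 monolayer sample and 1 spheroid sample of SNP cells was extracted with a Qiagen miRNA kit and labelled with Cy5 using a Toray 3D-Gene labelling kit, per the labels' protocols. Both samples were harvested by trypsin treatment of near-confluent cultures, per the same protocols. The spheroid culture was started from selected non-adherent cells, so selection and culture form cannot be told apart in this design. Each sample was hybridised to 1 array in 1 colour.

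The scanner tables deposited by the authors hold the median pixel intensity of each of 3200 spots at 635 nm, per the file headers, which also record straight-line fits between scans at 3 gains. These intensities were neither background corrected nor normalized between arrays. The scanner and its software are not given in the sources used here. The spots comprised 291 dog miRNA probes with 1 spot each, 1408 spots named blank, 181 named as having no probe, 32 negative controls, 16 spike controls and 2 further sets of 1106 and 166 spots whose contents are not given in the sources used here. No spot carried a warning mark. A second column, headed as background, tracked the spot itself, at a median of 0.816 and 0.833 of its intensity with log correlations of 0.973 and 0.971. It was therefore not treated as a local background and not subtracted.

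The value table deposited by the authors holds normalized intensities on a linear scale. Its construction was worked out by setting each column against the scanner values: the mean of the blank spots was subtracted, after leaving out the highest and lowest 5% of them, and the result was multiplied by 0.611 for the monolayer and 0.498 for the spheroids. These factors set the median of the miRNAs valued on both arrays to 25.0. All values matched that relation within 2.5e-05 percent. The medians over all valued miRNAs were 22.5 and 17.2, and the cells left empty were those of miRNAs at or below the detection limit described next. The table served as an alternative source of values.

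A miRNA was called detected on an array when its raw intensity exceeded the mean plus 2 SD of the blank spots, of which 1268 remained after leaving out the extremes. The blank mean was 85.1 on the monolayer array and 76.7 on the spheroid array. For the main values, the intensities of all spots were background corrected with limma's normexp method and an offset of 50, taken to log2, and quantile normalized over the 291 miRNAs. The offset pulls the differences of dim miRNAs towards 0. limma 3.58.1 in R 4.3.3 and numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15 were used, with matplotlib 3.10.9 for the plots.

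With 1 sample per culture, differences were described by size and no p-value was computed. A miRNA detected on both arrays was counted when its log2 difference was at least 1 in size. A miRNA detected on 1 array only was given as at least N-fold, its level over that of the dimmest detected miRNA of the other array on the same scale, the normalized or the deposited one, or, on the normalized scale, over its own level there if that was higher. In deposited units that floor was 3.06 in the monolayer and 1.60 in the spheroids. It was used in place of the detection limit itself (2.89 and 1.54), which the design had named, and gives slightly lower bounds. The spot-to-spot error came from 6 control probes with 8 spots each on both arrays. They were the spike controls and some probes of the set of 166 spots whose contents are not given. Their pooled SD of the log2 difference was 0.065 with 42 degrees of freedom, and the blank spots gave 0.08. Both SDs were taken from the background-corrected log2 values before quantile normalization, which covered the miRNAs only. After blank subtraction the dimmest of these controls had an SD of 0.245, against 0.074 over the other 5. These SDs leave out all variation between cultures, extractions and arrays.

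The design, the 24 miRNA lists, the rule for naming miRNAs and most alternatives were fixed before the data were examined. The rule named up to 12 miRNAs per direction that were 2-fold or more apart, the 5 largest lower bounds per direction among those detected on 1 array only, the 10 brightest of each array, the 4 members of each list with the largest absolute differences, and miR-210 and miR-21. Other members are named where a list needed them, and these were chosen after their values were seen. A probe named miR-199 without a letter was taken as a member of the fibroblast and smooth muscle list. For each list with at least 3 members detected on at least 1 array, the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 5 bins. A list of dog miRNAs with late-numbered names had 0 members on the array. Names are given as on the array, without the species prefix, and 290 of the 291 matched a gene of the RefSeq table of assembly UU_Cfam_GSD_1.0, used here only to find which miRNA genes neighbour each other. Positions in that table served only to measure the distance between miRNA genes and are not printed, since the array names no genome build. Probe sequences were not used here.

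The steps were tested on simulated data for the spheroid against monolayer comparison, with known changes in 40 of 166 miRNAs. Changes were put only into miRNAs well above the monolayer detection limit, so recovery of changes in miRNAs close to it was not tested. As many miRNAs were raised as lowered, by like sizes. A shift mostly to 1 side, or one that grows with brightness, was not simulated. The main values called 1 of 10 miRNAs raised 2-fold, 9 of 10 raised 4-fold, 1 of 10 lowered 2-fold and 5 of 10 lowered 4-fold, and 0 of 126 unchanged ones. Median log2 differences of 0.58 and -0.60 were found where 1 and -1 had been put in. Subtraction of the blank mean called 3, 10, 6 and 10 of these sets and 1 of the 126. Of 100 unshifted random lists, 99 lay inside the central range. They held only unchanged miRNAs but were ranked against a pool that included the changed ones. Their number therefore does not measure how often an unshifted list falls outside. A list of miRNAs all raised 2-fold lay at the 97.5th percentile, the edge of that range. A list inside the range may therefore still have shifted.

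The alternatives were no background correction, a normexp offset of 16, subtraction of the blank mean, scaling to the median or the 75th percentile, no scaling, the authors' value table, other detection limits and other sizes of difference. Scaling to the spike controls and a limit from the spots with no probe were added after seeing the data. The spike control scaling was applied to values with the blank mean subtracted, not to normexp values, so it changed the background treatment as well.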

Results

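MicroRNA levels were measured in SNP cells, which are canine mammary gland tumour cells, in 2 culture forms. The monolayer sample came from adherent cells, and the spheroid sample came from non-adherent cells of the growth medium that were selected and grown as spheroids without added matrix. Each form was represented by 1 total RNA sample, with an RNA integrity of 9.8 for the monolayer and 9.7 for the spheroids, labelled with Cy5 and hybridised to 1 array. Each array carried 291 dog miRNA probes with 1 spot each. The detection limit, taken from the blank spots, was an intensity of 89.8 on the monolayer array and 79.8 on the spheroid array. Above it lay 180 miRNAs (61.9%) in the monolayer and 201 (69.1%) in the spheroids. Of these, 178 were detected on both arrays, 2 in the monolayer only and 23 in the spheroids only, while 7.10% and 8.10% of the blank spots themselves lay above the 2 limits. The number of arrays limits the precision of every value: no difference had a replicate check, and no test across samples was made.

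The miRNAs that dominated the signal were largely shared. miR-21, a miRNA abundant in many carcinomas, was the brightest on both arrays and held 27.03% of the miRNA signal above background in the monolayer and 20.8% in the spheroids. In the authors' deposited values it stood at 7365 and 6119 intensity units, and because it ranked first on both arrays, quantile normalization fixed its log2 difference at 0. The 10 brightest miRNAs held 51.4% of the signal in the monolayer and 49.3% in the spheroids. miR-24, miR-23a, miR-23b, miR-27a and let-7a were among the 10 brightest on both arrays. let-7b, let-7c, let-7f and miR-16 were among them in the spheroids only, whereas miR-221, miR-27b, miR-125b and miR-106a were among them in the monolayer only. Across the 178 miRNAs detected on both arrays, log2 levels had a Pearson r of 0.949 and a Spearman rho of 0.899, which describe these 2 arrays, since miRNAs are not replicates.

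**Figure D1:**
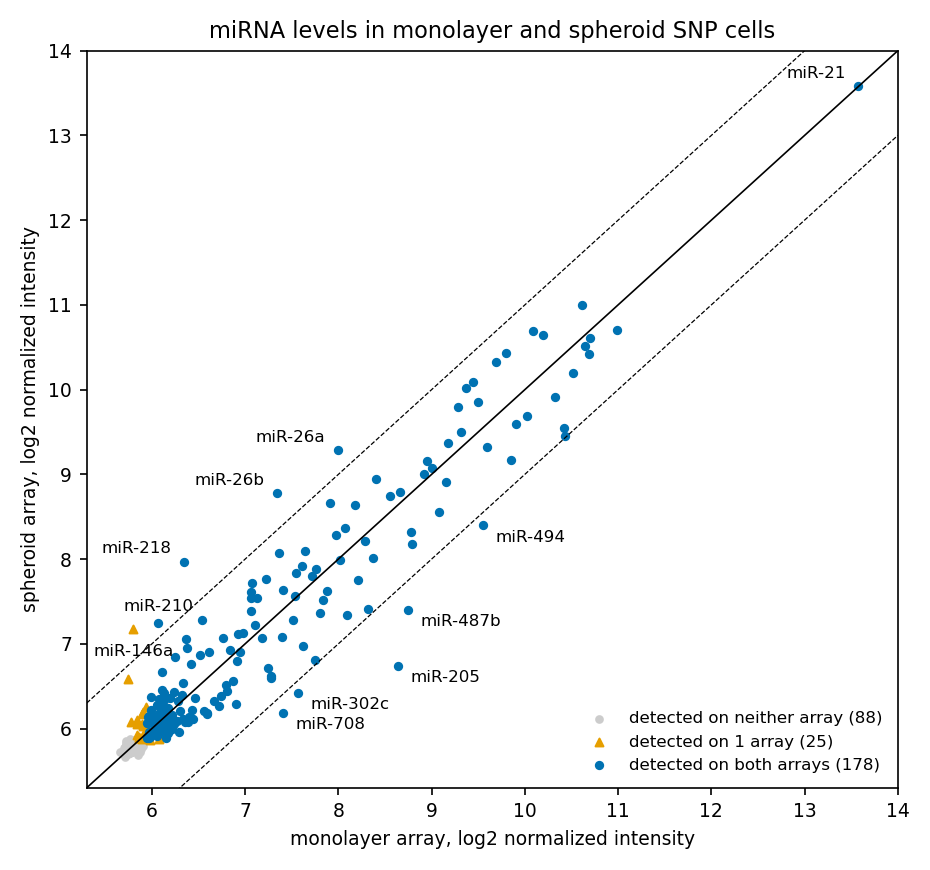
Log2 normalized intensity of 291 miRNAs on the monolayer array (horizontal axis) and the spheroid array (vertical axis), 1 array each. The solid line marks equal levels and the dashed lines a 2-fold difference; miR-218, miR-26b, miR-26a and miR-210 lie above the upper dashed line and miR-205, miR-487b, miR-708, miR-494 and miR-302c below the lower one. miR-146a, also above the upper line, was detected in the spheroids only.

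The comparison of the 2 cultures addressed how miRNA levels differ between the adherent and the spheroid form of these cells. miR-218, encoded within introns of SLIT genes, was 3.08-fold higher in the spheroid array, with a log2 difference of 1.62. miR-26b and miR-26a, which share a seed sequence, were higher by 1.44 and 1.30 on the log2 scale. Whether their probes read 1 shared signal was not tested. miR-210, a miRNA induced in cells under low oxygen, was higher by 1.18, from a monolayer spot close to the detection limit (raw intensity 93.4, under the blank mean plus 5 SD of 96.9). In the authors' deposited values, which keep dim spots further apart, miR-210 stood at 5.09 in the monolayer and 51.9 in the spheroids (10.2-fold), miR-218 at 12.5 and 112 (8.97-fold), miR-26b at 56.6 and 230.0 (4.06-fold) and miR-26a at 103 and 330.1 (3.22-fold).

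miR-205, a miRNA of basal and stratified epithelium, had the largest difference in the other direction in the main values, with a log2 difference of -1.90. Its deposited values were 170.0 in the monolayer and 27.6 in the spheroids. miR-708 was lower in the spheroid array by a log2 difference of -1.22, with deposited values of 60.0 and 9.41. In the deposited values its ratio of monolayer to spheroids (6.37-fold) was slightly larger than that of miR-205 (6.15-fold). miR-302c, a member of a miRNA cluster of pluripotent cells, differed by -1.15, with deposited values of 67.2 and 17.3. On the same list, miR-302a, miR-302b and miR-367 were detected on neither array. miR-487b and miR-494, both of the imprinted DLK1-DIO3 locus, differed by -1.35 and -1.15, with deposited values of 191 and 64.8 for miR-487b and 354 and 169 for miR-494.

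These 9 miRNAs, 4 higher and 5 lower in the spheroid array, were all that were 2-fold or more apart among the 178. All 9 kept their direction under the 8 other scalings and background treatments tried, and miR-205, miR-708, miR-218, miR-26b and miR-26a also stayed 2-fold or more apart in each. miR-210 was at 0.90 with the 75th percentile scaling and 0.94 without background correction, miR-494 at -0.79 with median scaling, -0.69 without scaling and -0.46 with the spike controls, and miR-487b just under 2-fold without scaling and at -0.95 with the spike controls. miR-302c was at -0.96 without background correction and -0.90 without scaling, and just under 2-fold with median scaling. All 9 were also 2-fold or more apart in the deposited values, in which 23 miRNAs were higher and 25 lower by that measure. Of those deposited differences, 14 of the 23 and 9 of the 25 involved a spot under the blank mean plus 5 SD on at least 1 array, and a spot at the detection limit had a deposited value of 2.89 in the monolayer against 1.54 in the spheroids. Repeated control spots gave a spot-to-spot SD of 0.065 for a log2 difference, and 58 miRNAs were higher and 64 lower by more than 2 such SDs. This measure covers spot error and not variation between cultures. Blank spots gave a larger SD of 0.08, so the limit may be too low for dim miRNAs. The split of calls depended on the scaling: it was 4 higher to 5 lower after quantile normalization, 9 to 3 with the arrays scaled to their median, 3 to 6 with the 75th percentile and 13 to 2 without scaling. With scaling to the spike control spots, chosen after seeing the data, it was 69 to 6. That setting used values with the blank mean subtracted, which gave 20 to 31 after quantile normalization. Its split and its median below are therefore not effects of scaling alone. The median log2 difference over the 178 miRNAs lay -0.23 from that of quantile normalization with the 75th percentile, 0.14 without scaling, 0.66 with the spike controls and -0.12 when the blank mean was subtracted instead of normexp.

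Among the miRNAs detected in the spheroids only, miR-146a, which is induced by NF-kB signalling, had the largest lower bound. Its deposited value was 46.8 in the spheroids, at least 15.3-fold the dimmest detected miRNA of the monolayer, or at least 2.35-fold on the normalized scale. Its relative miR-146b had a deposited value of 22.6, at least 7.39-fold by the same measure, or at least 1.56-fold on the normalized scale. A signal shared between the probes of miR-146a and miR-146b was not tested. miR-660, miR-421 and miR-152 followed, with deposited lower bounds of 3.74-fold, 3.12-fold and 2.90-fold but only 1.24-fold, 1.19-fold and 1.17-fold on the normalized scale. The 2 miRNAs detected in the monolayer only were dim: miR-135a-3p had a deposited value of 5.26, at least 3.29-fold the dimmest detected miRNA of the spheroids, and miR-632 one of 3.76, at least 2.35-fold. On the normalized scale these bounds were 1.14-fold and 1.07-fold.

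**Figure D2:**
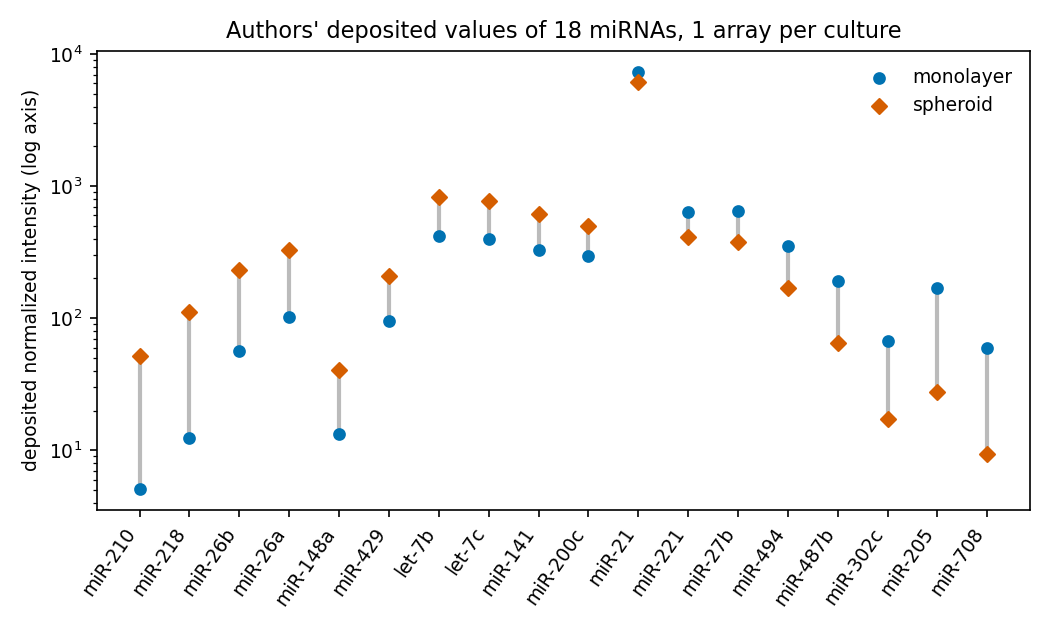
The authors' deposited normalized intensity (vertical axis, log scale) of 18 miRNAs in the monolayer (circles) and the spheroids (diamonds), 1 array each, ordered by their ratio. miR-210 spans 5.09 to 51.9 at the left end, and miR-205, at 170.0 and 27.6, and miR-708, at 60.0 and 9.41, close the right end.

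Of the 24 miRNA lists fixed before the data were examined, 3 families had medians above nearly all random lists in the main values. All 7 detected members of the let-7 family, which represses growth-promoting mRNAs such as those of RAS and HMGA genes, were higher, with a median log2 difference of 0.60. let-7e (0.65), let-7b (0.64) and let-7c (0.63) led it, and the deposited value of let-7b was 423 in the monolayer and 827 in the spheroids. All 5 members of the miR-200 family, which represses ZEB transcription factors in epithelial cells, were above 0, with a median of 0.51. Of these, miR-429 (0.75), miR-141 (0.64) and miR-200c (0.51) were bright, while miR-200a (0.01) and miR-200b (0.08) were close to the detection limit. These were at -0.36 and -0.26 with the 75th percentile scaling, and miR-200a was at -0.08 with median scaling. In the miR-15/16 family, which represses cyclin mRNAs, 4 of 6 detected members were higher, namely miR-15b (0.63), miR-195 (0.54), miR-15a (0.46) and miR-16 (0.45), and miR-503 and miR-497 were lower by log2 differences of -0.23 and -0.07, for a family median of 0.45. The dim miR-503 stayed lower in every setting, at -1.72 in the deposited values, where it was the only member 2-fold apart, -1.65 with the blank mean subtracted and -1.11 with the spike controls, whereas miR-497 was at -0.40 with the 75th percentile scaling and 0.46 with the spike controls. Among 10000 random lists of the same size and like brightness, the medians lay at the 99.2nd percentile for let-7, the 99.2nd for miR-200 and the 99.4th for miR-15/16. All 3 family medians stayed above 0 under each other background treatment and scaling, but their size depended on it. They were 0.59 to 1.46 for let-7, 0.49 to 1.36 for miR-200 and 0.43 to 1.39 for miR-15/16, highest with the spike controls. With the spike controls all 7 let-7 members were 2-fold or more higher, against 0 in the main values and 0 with the blank mean subtracted and quantile normalization. The percentiles were 97.9 to 99.6 for let-7, 89.6 to 99.2 for miR-200 and 91.3 to 99.8 for miR-15/16. The 8 settings amount to 5 distinct sets for these percentiles, since the median and 75th percentile scalings and no scaling shift all miRNAs alike, as do the deposited values and the spike controls. Above the central 95% of random lists lay let-7 in all 5 sets, but miR-200 and miR-15/16 in only 2 each.

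**Figure D3:**
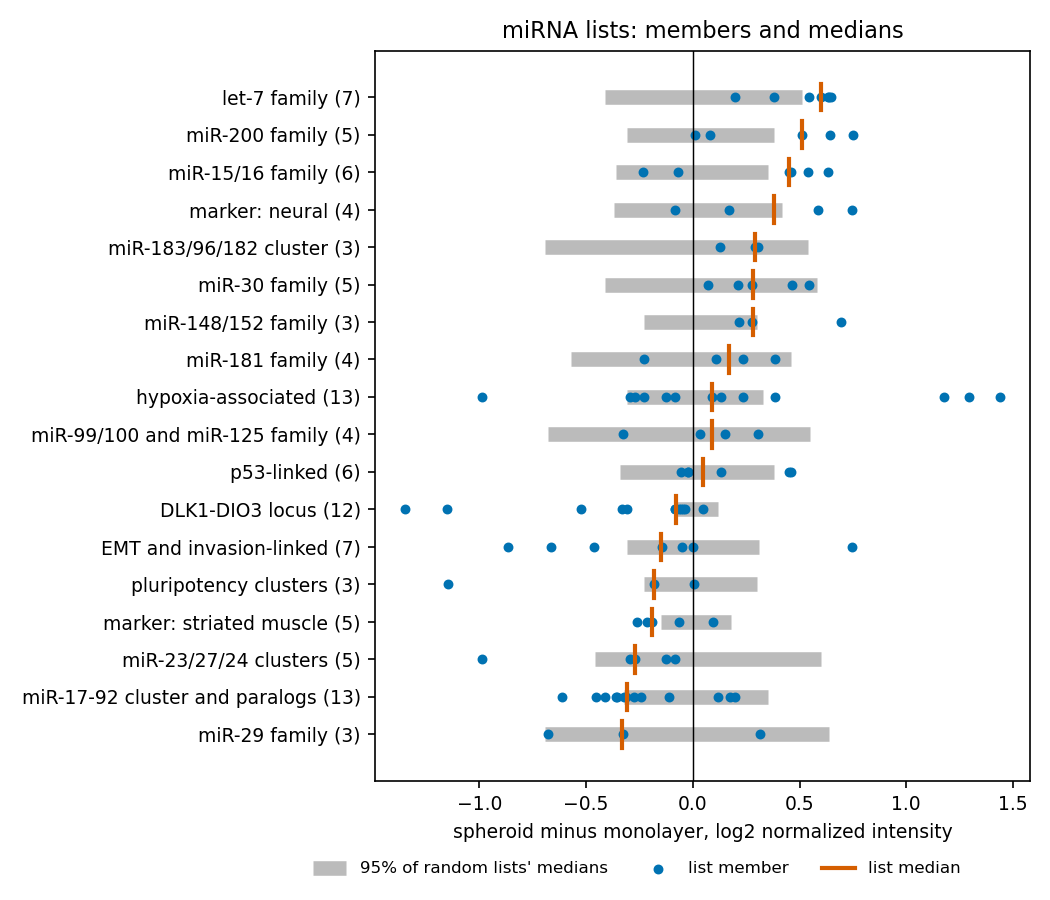
Log2 difference, spheroid minus monolayer, of the detected members (points) and the median (vertical bar) of the 18 lists with at least 3 detected members, with their number in brackets; grey bands span the central 95% of medians of random lists of like brightness. The let-7, miR-200 and miR-15/16 medians lie above their bands and that of the striated muscle markers below its band, while the medians of the miR-17-92, miR-23/27/24 and miR-29 lists, left of 0 here, lie right of 0 with median or spike control scaling or without scaling.

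The proliferation-linked miR-17-92 cluster and its paralogs went largely the other way, with 10 of 13 detected members lower, 3 higher and a median of -0.31 at the 4.10th percentile. miR-19a (-0.61), miR-18b (-0.45) and miR-106a (-0.41) were the lowest, and miR-106b (0.20), miR-93 (0.18) and miR-25 (0.12), which form a cluster of their own, were the higher members. The sign of this median depended on the scaling, being 0.08 with median scaling, 0.18 without scaling and 0.51 with the spike controls. All 5 members of the miR-23/27/24 clusters were lower, with a median of -0.27 at the 22.6th percentile, but only miR-27b (-0.99) stayed below 0 under every scaling, and the list median was 0.10 in the deposited values, 0.28 with median scaling, 0.38 without scaling and 0.71 with the spike controls. The miR-29 family, which represses collagen mRNAs, had miR-29a (-0.68) and miR-29b (-0.33) lower and miR-29c (0.31) higher, with a median at the 14.9th percentile that was 0.01 with median scaling, 0.10 without scaling and 0.42 with the spike controls.

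miR-221 and miR-222, which share a cluster and repress the cell cycle inhibitor p27, were lower by log2 differences of -0.87 and -0.46, although with spike control scaling miR-221 was at -0.03 and miR-222 at 0.30. Of the 7 miRNAs linked to epithelial-mesenchymal transition and invasion, 5 were lower, among them miR-155 (-0.66), miR-221 and miR-222, and miR-9 (0.75) was higher; the list median of -0.15 lay at the 10.2nd percentile and was -0.49 in the deposited values and 0.12 with the spike controls. Of the 35 members of the DLK1-DIO3 locus on the array, only 12 were detected on at least 1 array. Among these 12, 11 were lower (9 with the spike controls), with a median of -0.08 at the 3.18th percentile. Under the 8 other background treatments and scalings the median lay between -1.0, in the deposited values, and -0.06, and in 4 of the 5 distinct sets it lay below the central 95% of random lists, at percentiles of 0.24 to 2.24, against 3.54 without background correction. Over the 11 members detected on both arrays, the main median lay at the 20.9th percentile. miR-487b and miR-494 led it, followed by miR-370 (-0.52), which was at 0.08 without scaling and 0.41 with the spike controls, and miR-487a (-0.33), and most of the rest were close to the detection limit. In the deposited values a spot at that limit on both arrays would be 1.87-fold lower in the spheroids. The deposited list median of -1.0 was not told apart from that gap. Apart from miR-302c, the detected members of the pluripotency clusters were the dim miR-371 (-0.18) and miR-302d (0.00). miR-302a, miR-302b and miR-367 were detected on neither array. The list median of -0.18, at the 8.94th percentile, was -0.75 with the blank mean subtracted and -0.02 with the spike controls.

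Of the 13 hypoxia-associated miRNAs, 7 were higher, including miR-210, miR-26a and miR-26b, and 6 were lower, including miR-27b, with a median of 0.09 at the 62.2nd percentile. This split depended on the scaling: it was 10 higher to 3 lower with the 75th percentile, 11 to 2 in the deposited values and with median scaling (median 0.39 in both), and 12 to 1 without scaling (0.48) and with the spike controls (1.0), while the percentile stayed between 55.44 and 72.02. The p53-linked list had 3 of 6 detected members higher, including miR-15a and miR-16, with a median of 0.05 at the 58.0th percentile. With median scaling 4 of the 6 were higher (median 0.38), in the deposited values (0.29) and without scaling (0.47) 5, and with the spike controls all 6 (0.90), at percentiles of 55.7 to 88.1 over all settings. On this list miR-34a was at -0.02 (0.16 in the deposited values), and miR-34b and miR-34c were detected on neither array. Of its higher members, miR-15a and miR-16 also belong to the miR-15/16 family. The miR-30 family had all 5 members higher, led by miR-30c (0.55) and miR-30a (0.46), with a median of 0.28 at the 81.1st percentile, although the dim miR-30e (0.28) was at -0.01 with the 75th percentile scaling. The family median was 0.51 at the 94.1st percentile with an offset of 16, 0.89 at the 97.7th in the deposited values, just above the central 95% of random lists, and 1.5 at the 96.3rd with the spike controls. The cluster of miR-183, miR-96 and miR-182 had all 3 members higher, with miR-96 at 0.31 and miR-182 at 0.29, and a median at the 83.4th percentile, although the dim miR-183 (0.13) was at -0.23 with the 75th percentile scaling. The family of miR-148 and miR-152 had all 3 members higher, led by miR-148a (0.69, or 0.40 with the 75th percentile scaling), with a median of 0.28 at the 96.04th percentile. That median was -0.08 with the 75th percentile scaling, but 1.59 at the 97.7th percentile with the blank mean subtracted and 2.22 at the 98.1st with the spike controls, both above the central 95%, and 1.44 over the 2 members with deposited differences. The miR-181 family had a median of 0.17 at the 74.4th percentile and the miR-99/100 and miR-125 family one of 0.09 at the 57.4th, and these were -0.05 and -0.04 with the 75th percentile scaling, 0.32 and 0.25 in the deposited values and 0.93 and 0.86 with the spike controls.

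Markers of other cell types were mostly dim. The striated muscle markers had 4 of 5 detected members lower, among them miR-206 (-0.26) and miR-133c (-0.21), with a median of -0.19 at the 0.84th percentile, but their highest deposited value on either array was 10.1, and the percentile reached 11.8 under other settings. Their median was -0.85 in the deposited values and -0.86 with the blank mean subtracted, with 2 members 2-fold or more lower in each. A spot at the detection limit on both arrays would be 1.87-fold lower in the spheroids in the deposited values. The deposited median of these dim markers cannot be told apart from that gap. The neural markers had 3 of 4 detected members higher, including miR-9 and miR-338 (0.59), with a median of 0.38 at the 96.4th percentile. With the 75th percentile scaling 2 were higher and 2 lower, with a median of 0.07, while the median was 1.16 in the deposited values and 1.77 with the spike controls. The percentile was 92.6 to 97.3 under these settings, inside the central 95%, but 99.3 against random lists of miRNAs detected on both arrays, which is above it. The fibroblast and smooth muscle markers miR-199 (-0.31) and miR-214 (-0.21) and the blood cell markers miR-223 (-0.09) and miR-150 (-0.02) were lower, and all 4 were above 0 with spike control scaling. The other markers on these 2 lists, miR-143, miR-145, miR-142, miR-451 and miR-144, were detected on neither array. The same held for the neural miR-124, miR-137, miR-219-3p and miR-219-5p and the striated muscle miR-1, miR-208a and miR-208b. Of the endothelial markers, miR-126 was not detected on either array, and the other was miR-218, described above; the liver marker miR-122 was detected in the spheroids only, next to the limit, at a deposited value of 1.82. Of the 18 lists with at least 3 detected members, 3 lay above and 1 below the central 95% of random lists. By chance 0.9 in all would lie outside if the members of a list varied independently, as in random lists. Members with related sequences or neighbouring genes may not, so no excess over chance can be read from these counts.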

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

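The tests of the spike control shift in this part were all chosen after the result was seen.

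Spots outside the miRNA comparison carried signal. Of the 1106 spots of the larger unnamed control set, called QC-Probe on the array, 518 (46.8%) lay above the detection limit in the monolayer and 598 (54.1%) in the spheroids. Of the 166 spots of the smaller set, called S-Probe, 45 (27.1%) and 53 (31.9%) did. Among the 32 negative controls the numbers were 2 and 3, and 7.10% and 8.10% of the blank spots lay above the limits. What the 2 sets contain is not given in the sources used here. They were not counted as miRNAs, but some S-Probe spots entered the spot-to-spot SD, and QC-Probe spots are set against the miRNAs below.

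Relative to the 16 spike control spots, whose signal in the spheroids was 0.80-fold that in the monolayer (log2 SD 0.07 between spots), the 178 miRNAs detected on both arrays had a median log2 shift of 0.61, and 126 of them lay above 0. Background subtraction of dim spots is argued against, since the 36 brightest of the miRNAs had a median shift of 0.90. The miRNAs stood 0.52 above the shift of the 501 QC-Probe spots above the limit on both arrays, but this decides nothing about a factor common to the whole array, which cancels in a ratio to the spike spots. A higher miRNA content per unit of RNA in the spheroid cells remains a candidate explanation for the shift of 0.61, but it cannot be told apart from a difference in the amounts of RNA or spike added, which the labels do not give. The 2 spike controls and the 1 array per culture leave that open.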

How the results depend on the processing

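Scaling to the spike controls and the detection limit from spots with no probe were chosen only after the results were seen. The spike control scaling also changed the background treatment, as it used values with the blank mean subtracted. None of the values tried reversed a called difference: the 9 miRNAs 2-fold or more apart kept their direction under all 8 other backgrounds and scalings, and 5 of them stayed 2-fold apart in each. The counts moved more. Against 4 higher and 5 lower, there were 20 and 31 with the blank mean subtracted, 23 and 25 in the authors' table, 9 and 3 with median scaling, 13 and 2 without scaling, 69 higher with spike control scaling (6 lower) and 8 lower with a normexp offset of 16 (6 higher). A 1.5-fold limit gave 15 and 16 and a 3-fold limit 1 and 1, by construction. The other detection limits and filters gave 3 to 5 higher and 5 lower. The share of the 10 brightest was 40.5% and 40.6% without background correction, since the background then counts as signal. With an offset of 16, 1 list lay above the central 95% of random lists instead of 3, and 2 below it instead of 1; with members detected on both arrays only, 0 lay below it and 4 above, the fourth being the neural markers. The cause of these list changes was not tested. Detected miRNAs numbered 133 and 167 at 5 SD, and 156 and 179 with the limit from spots with no probe. Of the list medians, 18 of 23 moved by more than the spot error with the blank mean subtracted, 4 without background correction and 22 with spike control scaling. The planned use of single replicate spots was not run, as each miRNA has 1 spot. Signal over background limits the dim miRNAs: the blank SD was 2.37 and 1.55 intensity units, and a miRNA at the limit lies 2 SD above the blank mean. No paired analysis was possible because each culture had 1 sample.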

Other observations

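The tests of the family, hypoxia and miRNA choices in this part were chosen only after the results were seen, while those of the neighbouring spots, the spot noise and the neighbouring genes were set out beforehand.

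Several miRNAs outside the naming rule, chosen after their values were seen, also stood apart in the authors' deposited values. miR-130a was higher in the spheroids, at 56.8 in the monolayer and 128 in the spheroids, and so were miR-33a, an intronic miRNA of a sterol regulator gene, at 6.40 and 25.97, and miR-342, at 13.3 and 35.9. miR-22 was lower, at 82.3 and 29.4, as were miR-365, at 133 and 65.0, miR-139, at 35.7 and 12.6, and miR-505, at 54.3 and 22.9. Their main log2 differences were 0.71, 0.55, 0.58, -0.95, -0.91, -0.62 and -0.69 in that order, all under 2-fold.

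The let-7, miR-200 and miR-15/16 families had medians above most random lists, although 2 of the 6 miR-15/16 members were lower and only let-7 stood out in all 5 distinct sets of settings. Whether the families rose together was not tested. A trend with brightness left by the normalization was not tested independently: the let-7 median lay at the 99.2nd percentile of lists of like brightness, but the families were picked by that same percentile. Probes of near-identical let-7 members may read 1 shared signal: the differences of the 7 members had an SD of 0.17, above 2 times the spot error (0.13), but in the deposited values that SD was 0.13, below 2 times the matching spot error (0.15). The 7 members therefore cannot be told apart from fewer independent measurements. A difference in the state of the spheroid cells, or in the cells selected to form them, stays open and was not tested.

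For the miRNAs 2-fold or more apart, including miR-146a, uneven brightness around their spots is argued against, since the surrounding spots had a median log2 ratio of -0.005 in the direction of the miRNA. Where surrounding spots were blank, unevenness that scales with signal would show little in them, so it is not covered. The smallest of the differences among the 9 miRNAs detected on both arrays was 17.6 times the spot-to-spot SD, but the 2-fold limit by which they were picked fixes a ratio of that order, so it decides nothing about spot noise. Neither value reaches variation between cultures or extractions, which stays open with 1 sample each, so a link to culture form is only a hypothesis.

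A low-oxygen response in the spheroids is a candidate explanation for the higher miR-210. The hypoxia-associated list as a whole had its median at the 62.2nd percentile, and between 55.44 and 72.02 over all settings, with 7 of 13 members higher here, 11 in the deposited values and with median scaling, and 12 without scaling or with the spike controls. This neither bears the explanation out nor excludes it.

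Neighbouring miRNA genes may have differed alike through shared precursors. Over 84 pairs of genes within 10 kb with different miRNA numbers, the mean gap between the log2 differences of a pair was 0.24, against a median of 0.43 for random reassignments of like brightness, and 0 of 10000 were as low, a percentile of 0.0. Without the pairs inside the miR-17-92 list, whose members also have related sequences, 58 pairs had a mean gap of 0.28 against 0.35, at the 2.75th percentile, so related sequences stay open as part of the pattern.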
